A study of Mus musculus with 4 samples.

How the data were processed

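Gene expression was measured in 4 samples of differentiating C2C12 mouse myoblasts on Affymetrix GeneChip arrays, 1 array per sample. Per the labels, cells grew in medium with 25 mM glucose and 10% fetal bovine serum, were switched to 2% horse serum for differentiation, and were treated with vehicle (2 arrays), tranylcypromine (TC, 1 array) or S2101 (1 array) for 48 h. The labels state no dose. Per the labels' protocols, biotinylated cRNA was made from 250 ng of total RNA.

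The deposited values are MAS5 signal intensities per probe set on a linear scale, and MAS5 and Affymetrix Expression Console are the tools named in the submitters' processing notes. Versions, background settings and scan batches are not given in the sources used here, and detection calls were not used here. The deposited intensity values had a 2% trimmed mean of 500.0 on each array, as they have after scaling each array by 1 factor. Median signals were 75.1 and 66.6 on the control arrays, 63.4 with TC and 72.2 with S2101. The control arrays shared 1 identical value among 34945 probe sets and were counted as separate samples.

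Of 45101 probe sets, 64 were array controls, 34945 carried 1 gene symbol, 932 carried several and 9160 had none listed in the platform annotation. Gene identifiers of 34741 probe sets matched the mouse gene table (GRCm38.p6, used for names only), and 0 symbols needed an update. No genome was used, so no coordinates are given. Each of 18193 genes was represented by its probe set with the highest mean signal, and the 9097 genes with a mean signal over all 4 arrays at or above the median gene (178.8) were tested. Some list members, such as Gapdh, had no probe set with a single symbol and were not tested.

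Signals were turned into log2(signal + 50), the offset being 10% of the trimmed mean, with no further normalization. Differences are on this scale, which understates the change of dim genes. Testing used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend) with Benjamini-Hochberg adjustment at 0.05. The main fit compared the TC and S2101 arrays with the 2 controls (2 residual degrees of freedom plus a prior of 8.08). The sample descriptions number TC and S2101 as LSD1 inhibitor 1 and 2. Taking these arrays as replicates of LSD1 inhibition was a choice made here. A fit with 3 groups gave each compound against control and TC against S2101; it has 1 residual degree of freedom, from the control pair, plus a prior of 8.37, so the lone arrays are assumed to vary like the controls.

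The analysis fixed 24 gene lists, of which 20 had at least 3 tested members. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. Where stated, fry was also used to test for change in either direction, again without comparison with other genes. With an estimated correlation no list passed for any comparison. That setting tests on the residual degrees of freedom alone, 2 in the main fit and 1 with 3 groups, and so has little power. For oxidative stress genes the estimated correlation was 0.0013, below the preset 0.01, yet the camera p rose from 0.0065 to 0.107. Failing at this setting therefore says little about a list. Named genes were the 12 highest and 12 lowest past the test whose inhibitor arrays lay beyond both controls by at least 0.5, up to 4 members with the largest difference from the main lists and lists past camera and 2 from the others, Kdm1a, the 5 highest and 5 lowest for each compound, and the 5 largest differences each way between compounds that exceeded the control difference at least 2-fold. Exceptions are stated where they appear. The correlation of effects was set beside 1000 simulated draws of unchanged groups sharing the controls, and the overlap of calls beside 100.

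The fits were tested on simulated data for 9097 genes of which 200 were changed, in 20 draws. The inhibitor comparison recovered 84.6% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or more, with 5.37% of calls false. The TC comparison recovered 75.4% at 0.5 and 99.2% at 1, with 8.71% of calls false. Both simulated inhibitor arrays got the same change, with the spread of the fit with 3 groups. The rates therefore do not cover genes on which the compounds differ. Camera called a list shifted by 0.3 in 20 of 20 draws and called 0 other lists. The simulated genes varied independently, so these draws do not test camera on lists whose members vary together. In the data the estimated correlation was 0.51 for oxidative phosphorylation genes and 0.57 for cholesterol genes. These estimates rest on the 2 residual degrees of freedom of the main fit. Its residuals include the difference between TC and S2101, so a response to 1 compound would enter them too.

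Alternatives were offsets of 2% and 50% of the trimmed mean, no filter and a filter at the 75th percentile, quantile normalization, median centring, the mean over all probe sets of a gene (dim ones included), every probe set, no intensity trend, leaving out each array in turn, the number in the sample descriptions as a block, an estimated correlation and fry. The comparison of TC with S2101 has no replicate arrays on either side.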

Results

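C2C12 is a mouse myoblast line whose cells leave the cell cycle and fuse into myotubes once serum is lowered. The cells were moved to differentiation medium together with vehicle or with an inhibitor of the histone demethylase LSD1 (Kdm1a), and RNA was taken 48 h later. The inhibitors were tranylcypromine (TC), an amine oxidase inhibitor, and S2101, known here by its code name. Neither label gives a dose, so the compounds are not set side by side at matched doses. There were 4 arrays: 2 control arrays, 1 TC array and 1 S2101 array. MAS5 signals of 9097 genes were compared, and the number of arrays limits the precision of every value. Signals on log2 scale correlated across probe sets at r = 0.990 between the control arrays, at 0.990 between TC and S2101, and at 0.987 to 0.988 between a control and an inhibitor array. The ratio of 3′ to 5′ Gapdh signal, a sign of RNA integrity, was 0.782 and 0.770 on the control arrays, 0.790 with TC and 0.743 with S2101. Nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

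The first comparison asked which transcripts differed between the inhibitor arrays (n = 2, 1 per compound) and the control arrays (n = 2). On the log2 scale with an offset of 50, Ptgds, the lipocalin-type prostaglandin D synthase, had the largest increase, from signals of 239.7 and 181 on the controls to 3229.9 with TC and 2196 with S2101, a log2 difference of 3.39 ± 0.17 (SE; adjusted p = 6.24e-06, limma with Benjamini-Hochberg). Atp6v0e2, a subunit of the vacuolar proton pump, rose by 3.31 ± 0.15 (2.55e-06), and Csf2rb, a shared subunit of cytokine receptors, by 2.21 ± 0.19 (1.32e-04). With an offset of 2% of the trimmed mean Atp6v0e2 (3.69) exceeded Ptgds (3.61), so order and size depend on the offset. With offsets of 2% and 50%, Csf2rb stood at 2.90 and 1.10, and Ptgds at 2.67 and Atp6v0e2 at 2.33 with the larger. The cholesterol exporter Abca1 rose by 2.13 ± 0.33 (adjusted p = 0.00345, limma), with a wider error because its signal was 962 with TC and 2623 with S2101. Aspn, a small leucine-rich matrix proteoglycan, fell from 428 and 512 to 45.1 and 69.1, a log2 difference of -2.28 ± 0.18 (9.63e-05, limma). Its signal with TC lay below the offset of 50, so the size and rank of this fall depend on the offset too. The matrix gene Cilp fell by 2.20 on the log2 scale (SE 0.08; 7.12e-07), and the heparin-binding growth factor Ptn by 1.95 (SE 0.14; 6.73e-05).

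Of the 9097 genes, 729 passed the test (limma, Benjamini-Hochberg 0.05), 389 higher and 340 lower with the inhibitors. At least a 2-fold change was seen in 41 of them, 21 higher and 20 lower, a count that was 15 with a stricter filter, 21 with an offset of 50% of the trimmed mean and 67 over every probe set. An unadjusted p under 0.05 was found for 2029 genes. Among the other genes that rose most were the aldehyde dehydrogenase Aldh3a1 (log2 difference 1.93), the mitochondrial protein gene Chchd10 (1.86), the sterol reductase gene Tm7sf2 (1.75), the synaptic vesicle gene Syngr1 (1.70, but 0.08 in its other bright probe set) and xanthine dehydrogenase, Xdh (1.66). The hexose transporter Slc2a6 (1.60), Fam107a (1.51) and Fez1 (1.32) completed the 12 largest increases. With an offset of 50% of the trimmed mean Syngr1 stood at 1.03, Xdh at 0.93, Fam107a at 0.85 and Fez1 at 0.67. Among the genes that fell most were the matrix and matricellular genes Tnc (-1.71), Ccn2 (-1.67) and Prelp (-1.56), the actin-binding protein gene Tagln (-1.60) and the growth factor Igf1 (-1.25). The DNA repair gene Rad51ap1 (-1.37), the kinetochore gene Spc24 (-1.32), the cyclin gene Ccne2 (-1.27) and the sulfatase gene Arsj (-1.29) were also among the 12 largest decreases. Both inhibitor arrays lay beyond both controls in 51.1% of all genes tested, where chance gives 33.3% for 1 gene. Genes on an array can vary together, so a batch or culture shared by the inhibitor arrays could raise this share too. All 729 genes past the test also had both inhibitor arrays beyond both controls. With 2 arrays per group passing nearly requires this, so it adds no support. The count of genes past the test was 266 without the filter on dim genes, 423 without an intensity trend in the variance and 457 with a stricter filter. It was 468 when probe sets of a gene were averaged. Without the dim-gene filter the call of Abca1 ended (log2 difference still 2.13, adjusted p = 0.0777, limma). With averaged probe sets its log2 difference shrank to 0.89 and the call ended as well (adjusted p = 0.0588, limma). The other Abca1 probe sets in that average were dim, with mean signals of 42.8 and 17.5.

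**Figure D1:**
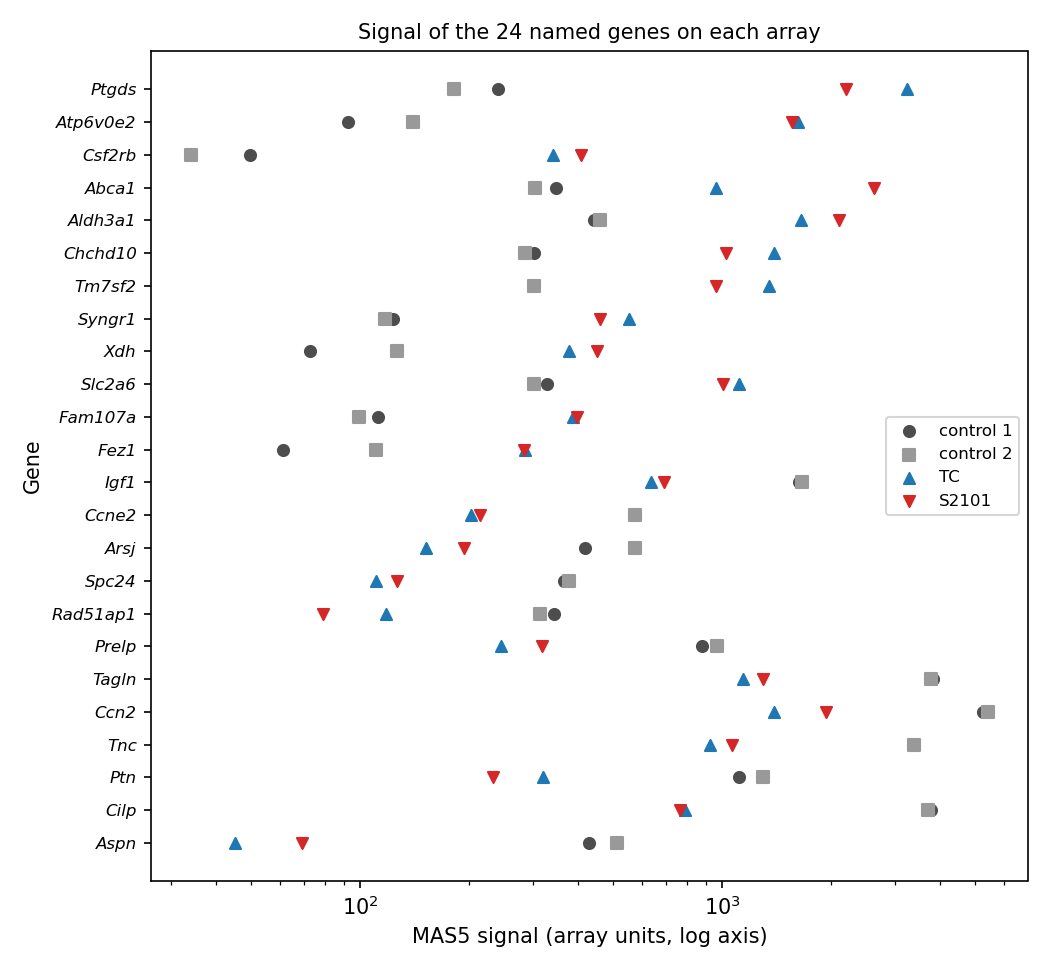
MAS5 signal (array units, log axis) of the 12 genes that rose most and the 12 that fell most, with one point per array for 2 control arrays, 1 TC array and 1 S2101 array. The genes were chosen to have both inhibitor arrays beyond both controls by at least 0.5 on the log2 scale. Examples are Ptgds (181 and 239.7 against 2196 and 3229.9) and Aspn (428 and 512 against 45.1 and 69.1).

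Genes of the cell cycle and DNA replication were lower with the inhibitors. Of 30 tested members, 21 fell and 9 did not pass over all genes tested, while adjusted over the list alone 27 fell; all 30 differences were negative, with a median of -0.67. Ccne2 fell by 1.27 on the log2 scale (SE 0.13; adjusted p = 3.55e-04, limma), and Birc5, which encodes survivin, by 0.97 (SE 0.10; 4.06e-04). The replicative helicase subunit Mcm5 (-0.95) and the proliferation marker Mki67 (-0.94, from signals of 1628 and 1575 to 798 and 824) fell by similar amounts. The list passed camera with a preset correlation of 0.01 (adjusted p = 1.65e-26) and fry (0.0281), but camera gave an adjusted p = 0.40 with an estimated correlation. On 2 residual degrees of freedom the estimated setting has little power, for this list and for those below. Among 13 cell cycle inhibitors and p53 targets, 2 rose, Trp53inp1 (0.61 ± 0.09) and Gadd45a (0.48 ± 0.07), 11 did not pass, and 3 were higher adjusted over the list alone; this list passed fry (adjusted p = 0.0281) but not camera (0.258).

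Extracellular matrix genes and part of the smooth muscle or myofibroblast markers were lower as well. Of 26 matrix genes, 17 fell and 9 did not pass, with a median of -0.38; adjusted over the list alone, 22 were lower and 1, Timp2, was higher. Tnc fell from 3373 and 3379.8 to 927 and 1067, Col1a1 by 1.19 on the log2 scale (SE 0.10; adjusted p = 1.33e-04, limma), the matricellular gene Postn by 0.95 and Col8a1 by 0.90. Of 7 smooth muscle or myofibroblast markers, 4 fell and 3 did not pass, and 5 were lower adjusted over the list alone. This list includes the matricellular genes Ccn1 and Ccn2, and its median of -0.90 is the value of Ccn1. Ccn2 fell from 5254 and 5410.1 to 1391 and 1938, Tagln by 1.60 on the log2 scale, the smooth muscle actin Actg2 by 0.92 and Ccn1 by 0.90. The smooth muscle genes Acta2 (-0.16), Mylk (0.09) and Smtn (-0.02), named after their values were seen, did not pass (adjusted p = 0.152, 0.842 and 0.944, limma). Both lists passed camera with the preset correlation (adjusted p = 3.04e-18 and 9.61e-07) and fry (0.0281 for each), but camera gave an adjusted p = 0.40 with an estimated correlation for each.

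Cholesterol synthesis and uptake genes were higher. Of 16 tested members, 10 rose and 6 did not pass, and adjusted over the list alone 14 were higher, with a median of 0.48. Mvd, the mevalonate pathway decarboxylase, rose by 0.68 ± 0.15 (adjusted p = 0.0195, limma), the squalene synthase gene Fdft1 by 0.63 ± 0.09 (0.00209), the isomerase gene Idi1 by 0.62 ± 0.15 (0.0379) and the sterol methyl oxidase gene Msmo1 by 0.61 ± 0.10 (0.00367). The list passed camera with the preset correlation (adjusted p = 1.34e-09), but neither fry (0.139) nor the other camera setting passed (adjusted p = 0.52 with an estimated correlation). The calls of Mvd and Idi1 ended when the TC array was left out (log2 differences 0.47 and 0.31; adjusted p = 0.107 and 0.0674, limma). The lipid desaturase Scd1, listed among adipocyte markers, rose from 14786 and 14020.0 to 23737 and 24328 (log2 difference 0.74 ± 0.06; 1.32e-04), as did the transcription factor Cebpb (0.42 ± 0.08); these were the only 2 adipocyte markers bright enough to test, and both were higher adjusted over the list alone.

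Of 13 genes of the unfolded protein and integrated stress response, 3 fell, 10 did not pass, and 5 were lower adjusted over the list alone, with a median of -0.15. The chaperone cofactor Sdf2l1 fell by 0.47 on the log2 scale (SE 0.11; adjusted p = 0.0232, limma), asparagine synthetase, Asns, by 0.45 (SE 0.08; 0.00751) and the transcription factor Atf4 by 0.29 (SE 0.07; 0.0257), while Chac1 stood at -0.38 ± 0.11 (0.0626). The list passed camera with the preset correlation (adjusted p = 0.00363; adjusted p = 0.40 with an estimated correlation) and fry (0.0281). The call of Atf4 ended when either control array (adjusted p = 0.170 and 0.106, limma) or the S2101 array (0.0576) was left out, and that of Sdf2l1 without control 1 (0.106) or the TC array (0.0934). Of 9 oxidative stress response genes, the glutathione transferase Gsta4 alone rose, by 1.20 ± 0.08 (4.59e-05, limma), and adjusted over the list alone 2 were higher; Gstm1 (0.41), Gclm (0.27) and Srxn1 (0.25) did not pass. That list passed camera with the preset correlation (adjusted p = 0.0217; adjusted p = 0.43 with an estimated correlation) and fry (0.0281), and no longer passed camera without the TC array (0.0691).

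**Figure D2:**
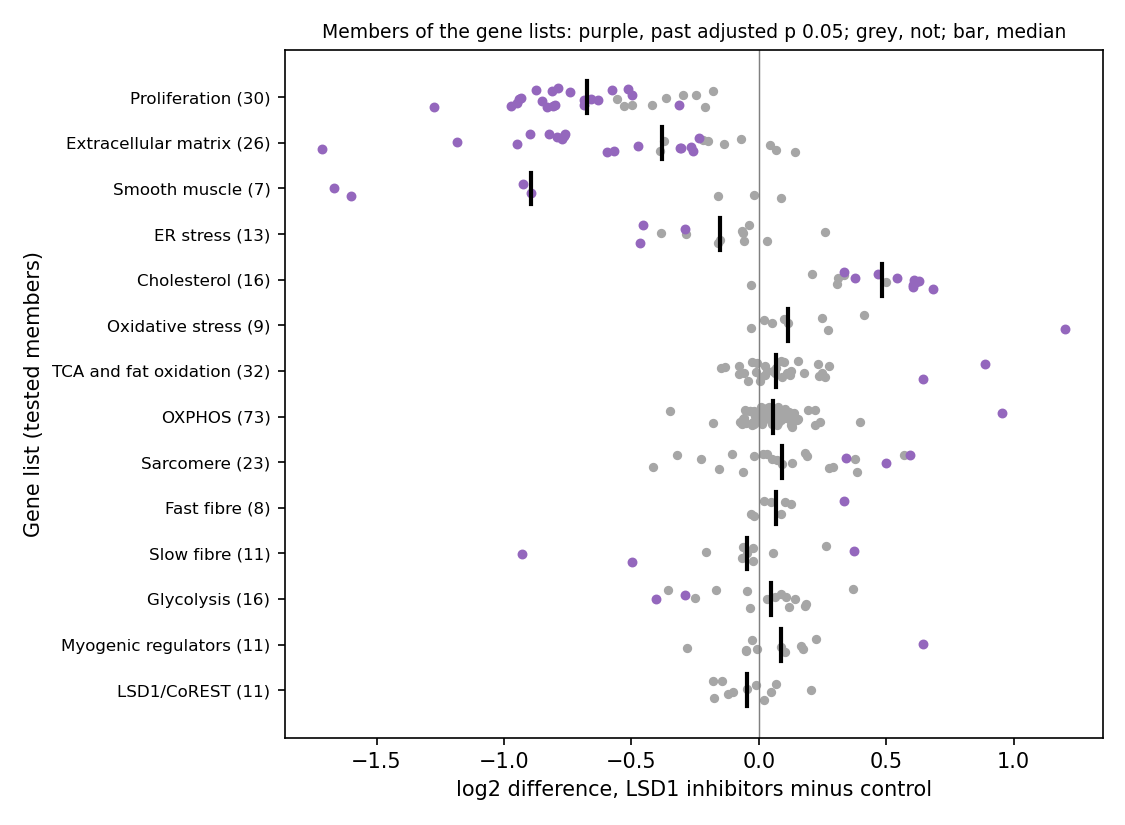
Log2 difference between the inhibitor and control arrays (horizontal axis) for each tested member of 14 gene lists (vertical axis, number of members in brackets), with purple points for genes past adjusted p 0.05, grey points for the others and a black bar at the median. The medians of the proliferation (-0.67), extracellular matrix (-0.38) and smooth muscle (-0.90) lists lie left of 0 and that of the cholesterol list (0.48) right of it. The smooth muscle list includes the matricellular genes Ccn1 and Ccn2, and its median is the value of Ccn1.

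Across the muscle lists some genes rose and others fell, and none of these lists passed camera with the preset correlation. Of 11 myogenic transcription factors, Eya1 rose (0.64 ± 0.11; adjusted p = 0.0060, limma), also adjusted over the list alone, and 10 did not pass, among them Mef2c (-0.28), Mef2d (0.22, but -0.41 in its other bright probe set) and Mef2a (0.17); camera gave an adjusted p of 0.420. Of 23 sarcomere, muscle membrane and developmental muscle genes 3 rose, the calcium release channel Ryr1 (0.59 ± 0.11), the acetylcholine receptor subunit Chrnb1 (0.50 ± 0.07) and Myom2 (0.34 ± 0.08), and 20 did not pass, among them the receptor subunit Chrnd (0.57 ± 0.17). Adjusted over the list alone, 7 of them were higher and 2 lower, and camera gave an adjusted p of 0.0975. The fast fibre gene Actn3 rose by 0.34 ± 0.07 (0.0141, limma), the only 1 of 8 fast fibre genes to pass, also over the list alone, while Myl1 (0.13), Myh1 (0.10) and Atp2a1 (0.09) did not (camera adjusted p = 0.314). Of 11 slow fibre genes, Myh7, the slow myosin heavy chain, fell from 561 and 628 to 281 and 295 (log2 difference -0.93 ± 0.12; 0.00165), Csrp3 fell by 0.50 on the log2 scale, the calcium pump Atp2a2 rose by 0.37, and Tnnt1 (0.26) was among 8 that did not pass; adjusted over the list alone 2 were higher and 2 lower (camera adjusted p = 0.420). Among 13 fusion and adhesion genes, the caveolin Cav3 (-0.84) and the integrin Itgb1 (-0.34) fell, the cadherin Cdh15 (0.31) and the integrin Itga7 (0.28) rose, and 9 did not pass, with equal counts adjusted over the list alone (camera adjusted p = 0.628). Tested for change in either direction, the sarcomere, slow fibre (fry adjusted p = 0.0116 for each) and fusion lists (0.0180) passed, and the lists of myogenic factors (0.0638) and fast fibre genes (0.0664) did not. This was not particular to muscle lists. Glycolysis and glucocorticoid lists also gave 0.0116 with this fry test, while oxidative phosphorylation (0.215) and CoREST lists (0.844) did not pass. Chrnb1, Myom2, Cdh15 and Itga7 were named after their values were seen. Without control 1 the call of Actn3 ended (adjusted p = 0.135, limma), and without control 2 those of Csrp3 (0.0645), Atp2a2 (0.0622) and Itgb1 (0.142). Of 2 other bright probe sets of Itgb1, 1 differed in the opposite direction (0.09) and 1 in the same direction (-0.13).

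Genes of energy metabolism showed few single changes. Of 32 genes of the TCA cycle and fatty acid oxidation, 2 rose, the pyruvate dehydrogenase kinase Pdk4 (0.89 ± 0.12; adjusted p = 0.00204, limma) and the fatty acid binding protein Fabp3 (0.64 ± 0.13; 0.0146), 30 did not pass, among them Etfdh (0.28) and Acadm (0.26), and 4 were higher adjusted over the list alone. Of 73 oxidative phosphorylation subunits, Cox7a1 rose, from 124 and 124 to 316 and 260.4 (0.96 ± 0.17; 0.0061, limma), also adjusted over the list alone, and 72 did not pass, among them Cox8b (0.40), Cox6a2 (-0.35) and Sdhd (0.24, but -0.23 in its other bright probe set). The lists had medians of 0.07 and 0.05, and both passed camera with the preset correlation (adjusted p = 0.0384 for each), but neither passed fry (0.231 and 0.444) or the other camera setting (adjusted p = 0.70 and 0.72 with an estimated correlation). Without the TC array the adjusted p values were 0.200 and 0.987, and without either control array they were also above 0.05, while the call of Fabp3 ended without the TC array (0.0599, limma). Of 16 glycolysis genes, the glucose transporter Slc2a1 (-0.40 ± 0.07) and Pgam1 (-0.29 ± 0.07) fell, and 14 did not pass, among them Pgam2 (0.37) and Pfkl (-0.36); adjusted over the list alone 1 was higher and 4 lower. Pgam1 lost its call without either control array (0.0877 and 0.190, limma) or the TC array (0.0581). The glycolysis median was 0.05 while the mean was -0.02 and the camera direction was down (adjusted p = 0.547), though the list passed fry for change in either direction (0.0116). None of 12 regulators of mitochondrial biogenesis passed over all genes or over the list alone (limma; Ppargc1b 0.44 ± 0.13, Pprc1 -0.23, Gabpa 0.18, Tfb1m 0.17; camera adjusted p = 0.759).

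The target gene itself, Kdm1a, had signals of 5537 and 5202 on the controls, 4990.2 with TC and 4862 with S2101, a log2 difference of -0.12 ± 0.07 that did not pass (adjusted p = 0.343, limma). Transcript level does not measure inhibition of the enzyme. None of 11 genes of LSD1 and its CoREST complex passed over all genes tested or over the list alone, among them Gse1 (0.21), Rcor3 (-0.18), Zmym3 (-0.18) and Hdac1 (-0.14), and camera gave an adjusted p of 0.424. The amine oxidases Maoa (0.15) and Smox (-0.09) did not pass over all genes or over the list alone. Of 18 glucocorticoid-responsive genes, the metal-binding metallothioneins Mt1 (0.64 ± 0.07) and Mt2 (0.58 ± 0.09) rose, the glucocorticoid-induced immunophilin Fkbp5 fell (-0.59 ± 0.12), 15 did not pass, among them Ddit4 (0.39), and 4 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.327; fry for either direction 0.0116). Markers of other cell types gave few tested genes. Among 5 neuronal genes Map2 rose by 0.39 ± 0.08 (0.0105, limma) and Nefl stood at -0.46 ± 0.15; over the list alone 1 was higher and 1 lower (camera adjusted p = 0.401; fry for either direction 0.0180). The osteoblast and cartilage marker Sox9 (0.15), the leukocyte marker Cd14 (0.07) and 3 interferon-stimulated genes, Irf9 (0.33) and Bst2 (0.25) among them, did not pass over all genes or over their lists alone (interferon camera adjusted p = 0.327). The call of Fkbp5 ended without control 2 (0.0501, limma) or the TC array (0.0533), and that of Map2 without control 1 (0.0579).

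Of 61 named genes past the test, 23 lost their call under at least 1 alternative. Without the filter on dim genes these were Abca1, Actn3, Atf4, Atp2a2, Cav3, Cox7a1, Csrp3, Eya1, Fabp3, Fez1, Fkbp5, Idi1, Itgb1, Msmo1, Mt2, Mvd, Pgam1, Ryr1 and Sdf2l1 (adjusted p from 0.0536 to 0.208, limma). With averaged probe sets they were Abca1, Atf4, Atp2a2, Eya1, Fabp3, Fdft1, Fkbp5, Itgb1, Map2, Ryr1, Slc2a1 and Trp53inp1 (adjusted p from 0.0588 to 0.556, limma). Averaging made each of these log2 differences smaller, for example 0.15 in Fdft1, 0.21 in Fabp3, 0.28 in Trp53inp1 and -0.27 in Fkbp5. The average takes in dim probe sets, whose differences lie nearer to 0 on this scale. A call lost this way therefore need not mean that bright probe sets disagree. Without an intensity trend the lost calls were Actn3, Atf4, Atp2a2, Fabp3, Idi1, Itgb1, Map2, Mvd, Pgam1, Sdf2l1 and Slc2a1 (adjusted p from 0.0534 to 0.138, limma). The call of Idi1 also ended with the stricter filter (0.0510, limma) and over every probe set (0.0779). Of the named genes past the test, 19 had other bright probe sets. All of these differed in the same direction by at least 50% of the size in 13 genes, while at least 1 was smaller in Atp2a2, Ccn1, Col1a1 (-0.57), Idi1 (0.31), Itgb1 and Syngr1, and 1 was opposite in Itgb1. Of 16 named genes that did not pass and had other bright probe sets, 4 had 1 in the opposite direction: Gabpa, Mef2d, Sdhd and Sox9.

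Each compound was then compared with the control pair, taking the lone array to vary like the controls. With TC, 744 genes passed (limma, Benjamini-Hochberg 0.05), 397 higher and 347 lower, led by Ptgds (3.66 ± 0.15; 2.95e-06), Atp6v0e2 (3.34), Csf2rb (2.10), Chchd10 (2.07) and Tm7sf2 (1.99). The largest decreases with TC were in Aspn (-2.45 ± 0.20; 2.27e-04), Cilp (-2.18), Ccn2 (-1.90), Tnc (-1.81) and Ptn (-1.76). With S2101, 610.0 genes passed, 307 higher and 303 lower, led by Atp6v0e2 (3.29), Ptgds (3.12), Abca1 (2.83 ± 0.13; 1.02e-05), Csf2rb (2.32) and Aldh3a1 (2.10). The largest decreases with S2101 were in Cilp (-2.22 ± 0.09; 6.87e-06), Ptn (-2.14), Aspn (-2.12), Tnc (-1.62) and Rad51ap1 (-1.56). Of 20 lists tested, 10 passed camera with TC and 5 with S2101, and 0 did so with an estimated correlation. Proliferation, matrix, smooth muscle, stress response and cholesterol genes passed with both compounds, and sarcomere, fast fibre, oxidative phosphorylation, TCA cycle and oxidative stress genes also passed with TC. Without the filter on dim genes only 12 genes passed with TC and 8 with S2101, with the calls of Aspn, Csf2rb and Ptn lost for both compounds and those of Atp6v0e2 and Rad51ap1 for S2101, and without an intensity trend 83 and 112 did.

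The responses to the compounds were then compared. Of the genes that passed, 216 were higher and 191 lower with both compounds, and 0 passed in opposite directions. Without the filter on dim genes only 2 were higher and 4 lower with both, and without an intensity trend 29 and 31. Independent lists of these lengths would share 13.4 and 11.6 genes. In 100 simulations of unchanged groups sharing these controls a mean of 0.08 genes passed with both compounds (at most 3), and lists of the observed lengths, ranked by the test, shared a mean of 51.4 higher genes (at most 68) and 45.6 lower genes (at most 58). Across genes, which are not independent replicates, the log2 differences correlated at r = 0.74 (rho = 0.63). Unchanged groups sharing these controls gave r = 0.33 on average in 1000 simulations (0.29 to 0.36). In both sets of simulations genes varied independently and only the controls were shared. They do not cover a batch or culture shared by the TC and S2101 arrays, which could also raise the overlap and r. The covariance was 0.0530 against 0.00564 simulated, a difference of 0.0474. When TC was set against control 1 and S2101 against control 2, r was 0.60 and the covariance 0.0469, and they were 0.56 and 0.0448 the other way round. With 2 controls they could not be divided with at least 2 on each side, so part of the overlap of calls may come from the shared controls. Over all 9097 genes, TC and S2101 differed by a median of 0.11 in size on the log2 scale, against 0.09 between the controls, and the 95% interval of the difference excluded a 2-fold difference in 8948. Most of the 9097 genes passed with neither compound, so these values do not show how alike the responses were. In genes that passed with TC or S2101 the medians were 0.17 between the compounds and 0.08 between the controls. Those calls depend on how far the arrays compared here lie apart, so these medians do not settle it either.

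**Figure D3:**
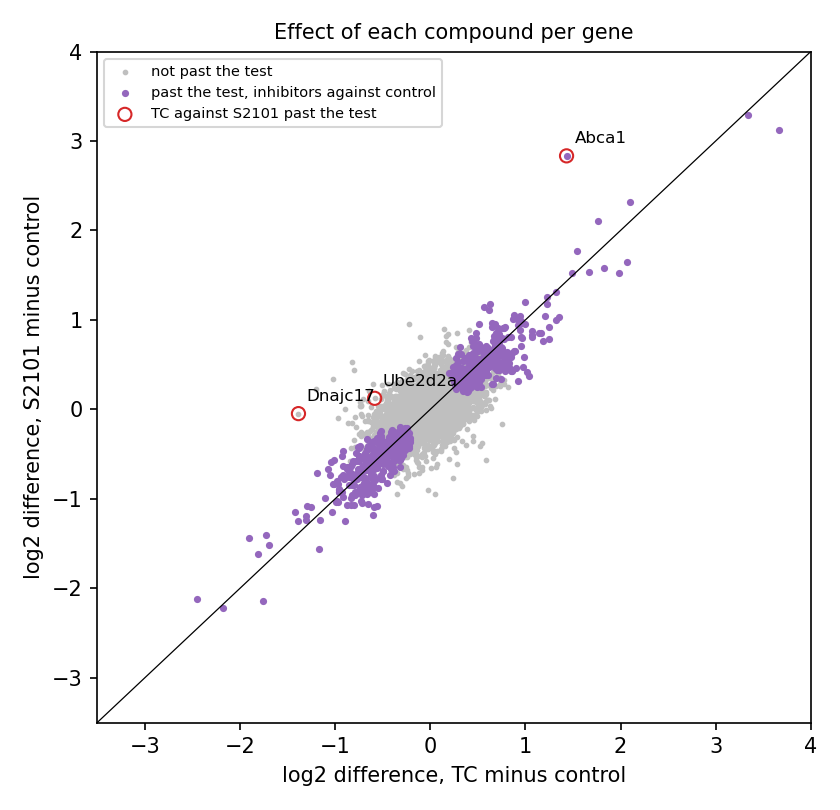
Log2 difference from control with TC (horizontal axis) against that with S2101 (vertical axis), one point per gene for 9097 genes, with purple points for the 729 genes past the test for the inhibitors together and red circles for the 3 genes that differed between the compounds. Abca1 lies above the line of equal effects (1.43 with TC, 2.83 with S2101); the purple points come from a fit whose error includes the difference between the compounds, which favours genes near that line.

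Set directly against each other, TC and S2101 differed in 3 genes (limma, Benjamini-Hochberg 0.05), all lower with TC, and 792 genes had an unadjusted p under 0.05. Abca1 was lower with TC by a log2 difference of -1.40 (95% interval -1.74 to -1.07; adjusted p = 0.0204, limma), although above the controls with both compounds. The cochaperone gene Dnajc17 had a signal of 1224 with TC against 3106, 3457 and 3170.5 on the control and S2101 arrays (-1.34, -1.58 to -1.10; 0.00304, limma). The ubiquitin-conjugating enzyme gene Ube2d2a, named after its values were seen, had 6253 with TC against 9310, 9485 and 10245 on the others (-0.71, -0.89 to -0.53; 0.0204, limma). Differences in Jpt1 (-1.37), Sncb (-1.35) and Matn2 (-1.24) did not pass (adjusted p = 0.0933, 0.109 and 0.109, limma), and 2 other bright probe sets of Jpt1 differed in the opposite direction. Pgm5 (1.16), Zdhhc14 (1.002), St7 (0.9997), Atg4d (0.93) and Htr2b (0.92) were higher with TC without passing. Of 20 lists, 10 passed camera with the preset correlation. Cholesterol genes had a median of 0.65 with TC and 0.30 with S2101, and oxidative phosphorylation genes 0.12 and about 0, with medians of the difference of 0.33 and 0.12 (adjusted p = 2.76e-08 for each; adjusted p = 0.565 with an estimated correlation for each). Without the dim-gene filter, or without an intensity trend, 0 single genes differed between the compounds, and with averaged probe sets 24 did, without Abca1, Dnajc17 and Ube2d2a (adjusted p = 0.128, 0.679 and 0.846, limma).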

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

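Of the tests in this part, those of a batch shared by the inhibitor arrays, of the fast fibre list and of all lists against random lists and of the oxidative phosphorylation and cholesterol lists after quantile normalization were chosen after the results were seen; the groups, fits, gene lists and most alternatives were fixed before the data were examined. The TC and S2101 arrays, 1 per compound, differed by a test of the difference itself in 3 genes and 10 gene lists (limma, Benjamini-Hochberg, and camera with a preset correlation). The spread came from the 2 controls alone (1 residual degree of freedom), so variation within a compound was not measured. The genes were Dnajc17 (adjusted p = 0.00304), Abca1 (0.0204) and Ube2d2a (0.0204), all lower with TC. Higher with TC were the lists of oxidative phosphorylation and cholesterol genes (camera adjusted p = 2.76e-08 for each), proliferation (0.0210), sarcomere, fast fibre and glycolysis genes (0.0239 for each), and TCA cycle with fatty acid oxidation and neuronal genes (0.0306 for each). Extracellular matrix and smooth muscle genes were lower with TC (0.0239 for each). With an estimated correlation, chosen for these counts after seeing the data, 0 of the 10 lists passed, and without the filter on dim genes or without an intensity trend 0 genes did. On 1 residual degree of freedom the estimated setting has very little power, so that list count says little.

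Single genes that differed between TC and S2101 could reflect one probe set. Among 3 other bright probe sets, all of Ube2d2a, 0 showed a difference of the same direction and at least 50% of the size, with values of -0.35, -0.03 and 0.14 against -0.71 for the one used. Abca1 and Dnajc17 have no other bright probe set, so for these genes a fault of 1 probe set and a difference between the compounds cannot be told apart. With 1 array per compound, variation between cultures stays open too, and no dose is stated.

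In 0 of the 10 lists was the median between the 2 controls as large as that between TC and S2101, for example -0.04 against 0.33 for cholesterol genes, but these lists were chosen for their difference between the compounds, so this count decides nothing. Of all 20 lists, 2 lay outside the middle 95% of 10000 random lists of the same size between the controls and 9 between the compounds; for fast fibre genes the control percentile was 98.75 against 97.56, and for oxidative phosphorylation genes 96.71 against 100. With 1 pair of controls, a difference between single arrays cannot be told apart from a response. After quantile normalization, which removes differences in signal distribution, 5 of the 10 lists still passed camera with the preset correlation. For the other lists such a difference cannot be told apart from a response. For oxidative phosphorylation and cholesterol genes the larger adjusted p was 1.66e-04 (camera, preset correlation), so equal signal distributions did not remove their difference. That p takes the members to vary almost independently, so what remained may still be variation between single arrays. A stronger response of these genes to TC may be one explanation, but larger variation between cultures and unequal doses stay open.

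The lower proliferation, matrix and smooth muscle genes with the inhibitors were also weighed. Under quantile normalization and median centring the list median nearest to 0 was -0.38. The arrays already had equal trimmed means, and the median log2 difference over all genes was 0.014. Neither setting could therefore move the lists much, so this check decides nothing about array scaling. The values show only that these lists lay below the tested genes as a whole. Of 43 members at or above the 75th percentile of signal 74.4% fell, against 66.7% of all 63 tested members. The fall was therefore not confined to the dimmer tested members. All 63 had already passed the filter on dim genes and the 43 were tested in a separate fit, so dim probe sets below that filter were not weighed. Hybridisation control probe sets differed by a median of -0.075 (9 probe sets, -0.17 to 0.13), but they bear only on hybridisation, no batch is given, and a batch of cells shared by the inhibitor arrays cannot be told apart from the treatment. An effect of LSD1 inhibition on these genes may account for the pattern, as a hypothesis from the same data.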

How the results depend on the processing

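The estimated correlation for per-compound list counts was chosen after seeing the data; the other alternatives were planned. Of 61 named genes past the test, 38 kept their call in every setting that tested them, 23 lost it in at least 1 and 0 reversed. Causes of the changes below were not tested (the cause was not tested in any), except that the stricter filter tests fewer genes and leaving out an array uses fewer samples. Counts per compound could not be tested without a control array, which leaves no residual degrees of freedom. At the 75th percentile the oxidative stress and interferon lists, and dimmer named genes, were left untested; low signal limits what could be tested.

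Counts for the inhibitors against control (729) were 266 without a filter, 457 at the 75th percentile, 468 with averaged probe sets, 423 without a trend and 501 to 749 leaving out 1 array. The 2-fold count (41) was 21 with the larger offset, 15 at the 75th percentile, 67 over every probe set. Without a filter, 12 genes passed with TC, 8 with S2101, 2 higher and 4 lower with both, 0 between compounds, and r was 0.556; without a trend these counts were 83, 112, 29, 31 and 0. Between compounds, 7 genes passed after quantile normalization, 10 after median centring, 24 with averaged probe sets and 8 over every probe set. Lists past camera were 0 in each comparison with an estimated correlation, 6 with TC at the 75th percentile, 8 with S2101 with averaged probe sets, and between compounds 6 without a filter, 5 after quantile normalization and 3 without a trend. With a replicate block by the numbers in the sample descriptions, which call TC inhibitor 1 and S2101 inhibitor 2, the inhibitor count was 1223. The control difference and the difference between TC and S2101 correlated at r = 0.065 across genes. With 1 pair on each side, this cannot show whether samples with the same number share a batch or culture.

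With an estimated correlation, list adjusted p values were 0.400 (proliferation, matrix, smooth muscle, stress response), 0.426 (oxidative stress), 0.522 (cholesterol), 0.699 (TCA cycle), 0.724 (oxidative phosphorylation) and, between compounds, 0.565 (cholesterol, oxidative phosphorylation). With fry they were 0.139 (cholesterol), 0.444 (oxidative phosphorylation), 0.231 (TCA cycle) and 0.0281 (cell cycle exit, now past). Oxidative phosphorylation and TCA cycle lists gave 0.108 and 0.176 at the 75th percentile, 0.0685 and 0.0507 after median centring, 0.109 and 0.0928 without a trend, and the TCA cycle list 0.0581 with averaged probe sets. Leaving out 1 array they ranged from 9.96e-06 to 0.987 and from 0.00536 to 0.200, the highest without TC; oxidative stress genes from 0.0163 to 0.0691. Sarcomere genes passed after quantile normalization (0.0474) and without S2101 (0.0197 to 0.397 leaving out 1 array), fast fibre genes without S2101 (0.0404 to 0.894).

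Reversed directions, none past a test, were fusion (0.562) and mitochondrial biogenesis (0.825) at the 75th percentile, fusion (0.922) with averaged probe sets, glycolysis and interferon (0.968) without a filter, and glycolysis (0.174 to 0.804 leaving out 1 array) and mitochondrial biogenesis (0.658 to 0.975) without S2101. Between compounds, cell cycle exit reversed at the 75th percentile (0.629) and after quantile normalization (0.841), stress response, fusion (0.718) and mitochondrial biogenesis (0.646) without a filter, and fusion (0.439), mitochondrial biogenesis (0.411) and oxidative stress (0.843) with averaged probe sets. With averaged probe sets Mef2d (-0.12), Smox (0.14), Srxn1 (-0.0085) and Zmym3 (0.021) reversed, and leaving out 1 array Cd14 (-0.065 to 0.21), Rcor3 (-0.36 to 0.0020), Zmym3 (-0.55 to 0.20), Gse1 (-0.0077 to 0.42) and Sox9 (-0.016 to 0.31).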

Other observations

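The 4 gene lists of this part, and therefore their tests, were chosen after the genes with the largest changes were seen but before the values of their members were. Of 25 tested lysosomal genes 6 rose and 19 did not pass, with a median of 0.21 (camera adjusted p = 2.06e-08; adjusted p = 0.0695 with an estimated correlation). The cathepsin genes Ctsa, Ctsb and Ctsd rose by 0.50 ± 0.07, 0.49 ± 0.06 and 0.45 ± 0.07, the peptidase gene Tpp1 by 0.47 ± 0.08, the proton pump subunit Atp6v1a by 0.43 ± 0.08 and the hexosaminidase gene Hexa by 0.41 ± 0.07 (adjusted p from 0.00137 to 0.0111, limma). Of 15 genes of fatty acid synthesis and desaturation 5 rose and 10 did not pass, with a median of 0.26 (camera adjusted p = 1.34e-04; adjusted p = 0.0912 with an estimated correlation); among the 5 were Elovl6 (0.49 ± 0.10), Fads1 (0.47 ± 0.09) and Acly (0.30 ± 0.07).

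The increase of Atp6v0e2 raised the hypothesis that lysosomal genes rose together. Camera gave an adjusted p of 2.06e-08 over the 3 added lists with enough members (0.0695 with an estimated correlation). The call rests on the preset correlation, and the estimated setting had little power here. The higher cholesterol genes and Scd1 raised the hypothesis that fatty acid synthesis genes rose too, with an adjusted p of 1.34e-04 (0.0912 with an estimated correlation); a shared change of lipid synthesis genes may be one reading. The lower Ccn1, Ccn2, Tagln and Tnc raised the hypothesis that targets of TGF-beta, YAP or SRF fell together. Of 20 such genes 3 fell, Fhl2 (-0.60), Flna (-0.34) and Tpm4 (-0.33), 17 did not pass, and the median was -0.10, so the shift was small although camera gave 3.94e-04 (0.0912 with an estimated correlation). The higher Abca1 raised the hypothesis that LXR targets rose together, but Pltp (0.35, adjusted p = 0.0418, limma) was the only tested member of 8, too few to decide.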
